A study of Homo sapiens with 12 samples.

How the data were processed

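Bulk RNA-seq libraries had been made from islet-like cells derived from expandable pancreatic progenitors of the human embryonic stem cell line MEL1, at day 8 in the medium named R6. The 12 libraries fall into 4 groups of 3: CLEC16A knockout (KO) with its wild type (WT), and NKX2-2 KO with its own WT. Groups and replicate numbers were taken from the sample titles. Nothing in the labels says whether replicates came from separate cultures, so p-values measure the spread between these libraries, which may be technical. The sample titles name no edited clone, so differences between cell lines cannot be told apart from effects of the knockout. A knockout effect below means the difference between libraries labelled knockout and wild type.

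The authors deposited, for each experiment, a table of raw counts per Ensembl gene and a table of TPM (transcript abundances scaled to a fixed total). Per the submitters' processing notes, fastp 0.22.0, HISAT2 2.2.1 and StringTie 2.1.7 were used with the genome build hg38. The program that counted the reads, the annotation release and the use of strand are not given in the sources used here, so reads of overlapping or antisense genes cannot be separated. The tables of the experiments differ in what they hold. The deposited TPM values of the listed genes add up to 41.5% to 47.3% of the full TPM total in the NKX2-2 libraries and to 99.7% to 99.8% in the CLEC16A libraries. All 37 mitochondrial DNA genes are at 0 counts in the CLEC16A libraries. Counts per TPM were compared between experiments for 11060 genes with a mean TPM of at least 2 in both and a mean count of at least 200 in either, and 208 of them had at least 4 times fewer counts per TPM in the NKX2-2 tables, CHGA among them. Counts of such genes are uncertain there. The 45 rows of Y copies of pseudoautosomal genes were left out. All columns belonged to a sample.

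Differential expression was tested within each experiment on the deposited counts with edgeR 4.0.16 (quasi-likelihood F test, robust, TMM scaling, filterByExpr) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. Genes with an absolute log2 fold change of at least 1 (2-fold) were counted as well. Standard errors (SE) are the absolute log2 fold change over the square root of F. The difference between both knockout effects was tested as an interaction in one edgeR fit of the 12 libraries. Levels are CPM (counts scaled to library size) on TMM-scaled library sizes, as mean ± SD with 3 libraries per group. A fold against a group at 0 counts was computed against a floor of 3 counts per library and is a lower bound, for counting error only, as is each 95% counting interval.

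The 34 gene lists (33 of them testable in the CLEC16A experiment), the designs and most alternatives were fixed before the data were examined. Lists were tested with camera (limma 3.58.1, log2 CPM with a prior count of 2, preset correlation 0.01), with an estimated correlation and with fry as alternatives, and the knocked out genes were left out of them. Camera compares the genes of a list with all other genes. By contrast, fry asks only whether the genes of a list changed, so lists pass it easily where many genes changed. The genes named are the knocked out genes, 15 hormone and identity genes, the 6 largest rises and 6 largest falls among genes with adjusted p under 0.05, a mean of at least 5 CPM in the higher group, groups that do not overlap and a symbol that is no clone, accession or read-through name, and the members of each described list with the smallest p. Some of these genes are not reported here. Library measures were compared with two-sided exact permutation tests, whose smallest p with 3 against 3 is 0.1. Alternatives were DESeq2 1.42.0, RLE and upper-quartile scaling, other count filters, a replicate block, one fit of all libraries, limma on log2(TPM + 1) and log2(TPM + 0.1), and leaving out each library. Added after seeing the data were fits without both libraries numbered 3, without the genes short of counts and without mitochondrial DNA genes, and list tests under RLE and upper-quartile scaling.

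The fits were tested on simulated counts drawn, independently for each gene, from the wild type means and the real library sizes and spread. Few genes were changed, with as many raised as lowered. In the NKX2-2 simulation, 94 tested genes were changed 2-fold and 96 were changed 4-fold. In the real data 33.4% of genes were called in the NKX2-2 and 45.0% in the CLEC16A experiment, so the rates below need not hold there. In the NKX2-2 simulation over 16779 genes, edgeR recovered 85.1% of the 2-fold and 99.0% of the 4-fold changes, and 5.91% of its calls were false. In the CLEC16A simulation over 19304 genes it recovered 75.3% and 96.9%, with 6.21% of calls false. In that of the difference of effects over 19558 genes it recovered 61.6% and 81.4%, with 3.45% false. Of the calls of DESeq2, 6.08% were false in the NKX2-2 simulation over 17436 genes and 9.44% in the CLEC16A simulation over 19958 genes. Coordinates are from GENCODE 29 on hg38.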

Results

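Transcript levels were measured by RNA-seq in islet-like cells made from MEL1 expandable pancreatic progenitors, with and without knockout of NKX2-2, a homeodomain transcription factor of islet cells, or of CLEC16A, a regulator of mitophagy. Each group held 3 libraries. Total counts per library ran from 16158286 to 20654720 in the NKX2-2 experiment and from 31364272 to 33763795 in the CLEC16A experiment. Every pair of replicates differed by more than sampling noise. Of 11 comparisons of library measures, 4 reached the smallest exact permutation p this design can give (p = 0.1, Benjamini-Hochberg adjusted 0.275, with SD and n = 3 below). In the NKX2-2 experiment, mitochondrial DNA genes took 9.76% ± 0.55 of counts in knockout and 7.55% ± 0.48 in wild type libraries. Of the counts outside mitochondrial DNA, the 10 most abundant genes of each library took 4.78% ± 0.33 and 4.06% ± 0.31, and histone genes 0.0815% ± 0.0022 and 0.116% ± 0.0061. In the CLEC16A experiment the 10 most abundant genes of each library took 5.53% ± 0.049 in knockout and 6.05% ± 0.18 in wild type libraries.

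The targeted genes were examined first. NKX2-2 (ENSG00000125820, chromosome 20, 21511010 to 21514026, minus strand) was at 75.97 ± 13.7 CPM in knockout and 95.01 ± 1.63 CPM in wild type libraries of its own experiment, a log2 fold change of -0.32 (SE 0.12, adjusted p = 0.06096). The 3 knockout libraries held 91.8, 67.9 and 68.2 CPM. This difference did not pass the edgeR test, but it did in 7 of the 19 alternatives, over which the adjusted p ran from 0.00192, with a replicate block, to 0.235. The log2 fold change was -0.50 without KO replicate 1 (adjusted p = 0.0023) and -0.74 with limma on log2(TPM + 1) (adjusted p = 0.00558). CLEC16A (ENSG00000038532, chromosome 16, 10944488 to 11182189, plus strand) was at 36.7 ± 1.34 CPM in knockout and 32.3 ± 3.35 CPM in wild type libraries, a log2 fold change of 0.18 (SE 0.09, adjusted p = 0.0949), with adjusted p = 0.0335 without WT replicate 1 (up to 0.940 over the 18 alternatives) and a log2 fold change of 0.019 with limma on log2(TPM + 1). Transcript levels per gene therefore do not check the knockout labels, and the groups below are the libraries labelled knockout and wild type. NKX2-2 transcripts fell 1.91-fold in the libraries labelled CLEC16A knockout, a log2 fold change of -0.93 (SE 0.07, adjusted p = 3.53e-10). CLEC16A in the NKX2-2 experiment had a log2 fold change of 0.05 (SE 0.14, adjusted p = 0.817).

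The first comparison asked what changed in cells labelled NKX2-2 knockout. GCG, which encodes glucagon, fell 21.5-fold (60.9 ± 13.2 CPM in knockout and 1310.2 ± 142 CPM in wild type libraries), a log2 fold change of -4.43 (SE 0.17, adjusted p = 4.02e-09). TPH1, the rate-limiting enzyme of serotonin synthesis outside the brain, fell 6.02-fold, PPY (pancreatic polypeptide) 6.35-fold and INS (insulin) 2.61-fold. SST, which encodes somatostatin, rose 4.64-fold (112 ± 8.399 CPM in knockout and 24.1 ± 5.85 CPM in wild type libraries), and NEUROG3, the transcription factor of endocrine progenitors, rose 7.13-fold (51.3 ± 6.37 CPM in knockout and 7.18 ± 1.72 CPM in wild type libraries).

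Among the transcription factors, NKX6-1 had a log2 fold change of -1.89 (SE 0.12, adjusted p = 1.87e-07) and PDX1 of -1.20 (SE 0.13, adjusted p = 1.26e-05), both lower. MAFA rose, with a log2 fold change of 1.64 (SE 0.15, adjusted p = 3.74e-06). The log2 fold change was -0.29 (SE 0.15, adjusted p = 0.149) for GHRL (ghrelin) and -0.10 (SE 0.10, adjusted p = 0.517) for NEUROD1, which did not pass the test, and IAPP was too low to be tested. CHGA (chromogranin A) had a log2 fold change of -1.56 (SE 0.12, adjusted p = 8.94e-07), but its counts fall short of its TPM in these tables. INS overlaps the read-through gene INS-IGF2, so its counts are uncertain in both experiments.

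Of the 29 tested beta cell identity genes, 4 rose, 21 fell and 4 did not pass the test (4 higher and 22 lower adjusted over the list alone), with a median log2 fold change of -1.02 (camera adjusted p = 1.32e-06, and adjusted p = 0.0825 with an estimated correlation). The smallest p belonged to PCSK1 (-4.05) and SYT13 (-3.56), with log2 fold changes in parentheses here and below. PCSK1 encodes a proinsulin convertase. Of the 15 tested alpha cell genes, 2 rose, 7 fell and 6 did not pass the test (3 higher and 7 lower adjusted over the list alone), with a median log2 fold change of -0.33 (camera adjusted p = 0.0184, and adjusted p = 0.162 with an estimated correlation). The leading members were GCG (-4.43) and IRX1 (-3.99). Of the 11 tested genes of enterochromaffin-like cells, 0 rose, 11 fell and 0 did not pass the test (0 higher and 11 lower adjusted over the list alone), with a median log2 fold change of -2.31 (camera adjusted p = 5.86e-11, and adjusted p = 0.0359 with an estimated correlation). They were led by ADRA2A (-3.45) and LMX1A (-2.70). Of the 9 tested delta cell genes, 7 rose, 1 fell and 1 did not pass the test (7 higher and 1 lower adjusted over the list alone), with a median log2 fold change of 0.87 (camera adjusted p = 0.00278, and adjusted p = 0.129 with an estimated correlation). LEPR, the leptin receptor, led with 2.95, before FRZB with 2.37. Of the 14 tested pancreatic progenitor genes, 1 rose, 10 fell and 3 did not pass the test (1 higher and 11 lower adjusted over the list alone), with a median log2 fold change of -0.95 (camera adjusted p = 3.15e-05, and adjusted p = 0.241 with an estimated correlation). Its first members were MNX1 (-2.49) and NKX6-1 (-1.89). Of the 29 tested genes of monogenic diabetes, 1 rose, 17 fell and 11 did not pass the test (1 higher and 17 lower adjusted over the list alone), with a median log2 fold change of -0.65 (camera adjusted p = 6.50e-05, and adjusted p = 0.189 with an estimated correlation). The members with the smallest p went opposite ways, MNX1 (-2.49) and NEUROG3 (2.83).

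Of the 24 tested genes of secretory granules and exocytosis, 2 rose, 17 fell and 5 did not pass the test (4 higher and 17 lower adjusted over the list alone), with a median log2 fold change of -1.01 (camera adjusted p = 4.07e-06, and adjusted p = 0.0825 with an estimated correlation). SYT13 (-3.56) was joined by SLC18A2 (-2.63), a vesicular monoamine transporter. Of the 18 tested ion channel genes, 2 rose, 11 fell and 5 did not pass the test (2 higher and 11 lower adjusted over the list alone), with a median log2 fold change of -0.91 (camera adjusted p = 0.001103, and adjusted p = 0.486 with an estimated correlation). These included ITPR3 (-3.02). Of the 23 tested interferon and antigen presentation genes, 0 rose, 19 fell and 4 did not pass the test (0 higher and 19 lower adjusted over the list alone), with a median log2 fold change of -1.28 (camera adjusted p = 3.11e-11, and adjusted p = 0.0359 with an estimated correlation). MX1 and IFI6, both induced by interferon, had -2.86 and -2.94. Of the 16 tested NF-kB and inflammation genes, 1 rose, 12 fell and 3 did not pass the test (1 higher and 13 lower adjusted over the list alone), with a median log2 fold change of -0.76 (camera adjusted p = 1.32e-06, and adjusted p = 0.129 with an estimated correlation). They were led by ICAM1 (-2.59) and CXCL8 (-1.93). Of the 26 tested glycolysis and hypoxia genes, 2 rose, 21 fell and 3 did not pass the test (2 higher and 21 lower adjusted over the list alone), with a median log2 fold change of -0.54 (camera adjusted p = 1.32e-06, and adjusted p = 0.263 with an estimated correlation). ALDOC and ENO2, glycolytic enzymes, had -2.57 and -1.39. Of the 22 tested cholesterol synthesis genes, 0 rose, 15 fell and 7 did not pass the test (0 higher and 17 lower adjusted over the list alone), with a median log2 fold change of -0.46 (camera adjusted p = 5.28e-06, and adjusted p = 0.0825 with an estimated correlation). Among them was DHCR7 (-0.997). Of the 15 tested immediate early genes, 2 rose, 8 fell and 5 did not pass the test (2 higher and 8 lower adjusted over the list alone), with a median log2 fold change of -0.50 (camera adjusted p = 0.0108, and adjusted p = 0.145 with an estimated correlation). FOS had -1.95 and NR4A2 -1.40.

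Of the 18 tested mesenchyme genes, 15 rose, 2 fell and 1 did not pass the test (15 higher and 2 lower adjusted over the list alone), with a median log2 fold change of 1.27 (camera adjusted p = 3.42e-08, and adjusted p = 0.145 with an estimated correlation). PDGFRA, a growth factor receptor of mesenchymal cells, had 3.31 and LUM, a matrix proteoglycan, 1.97. Of the 7 tested endothelium and blood genes, 5 rose, 1 fell and 1 did not pass the test (5 higher and 1 lower adjusted over the list alone), with a median log2 fold change of 1.42 (camera adjusted p = 0.0209, and adjusted p = 0.175 with an estimated correlation). These were led by CLDN5 (1.80) and KDR (1.37). Of the 9 tested acinar genes, 5 rose, 0 fell and 4 did not pass the test (5 higher and 0 lower adjusted over the list alone), with a median log2 fold change of 0.67 (camera adjusted p = 0.0283, and adjusted p = 0.528 with an estimated correlation). CLPS had 3.70 and PRSS2, which shares reads with other trypsinogen genes, 1.49. The acinar call was lost without KO replicate 3 (adjusted p = 0.0633) or WT replicate 2 (adjusted p = 0.0556; from 0.0107 to 0.528 over the 14 alternatives). Of the 13 tested protein genes of mitochondrial DNA, 6 rose, 0 fell and 7 did not pass the test (7 higher and 0 lower adjusted over the list alone), with a median log2 fold change of 0.32 (camera adjusted p = 0.0101, and adjusted p = 0.528 with an estimated correlation). MT-ND3 had 0.66 and MT-CO3 0.71. The other lists did not pass, with camera adjusted p of 0.427 for epsilon and PP cell genes (4 higher and 3 lower of 10), 0.0798 for endocrine progenitor genes (2 higher and 6 lower of 16), 0.444 for duct genes (5 higher and 7 lower of 18), 0.838 for intestine and stomach genes (3 higher and 3 lower of 9), 0.525 for liver genes (6 higher and 5 lower of 17), 0.469 for neuronal genes (6 higher and 4 lower of 16), 0.469 for pluripotency genes (2 higher and 1 lower of 9), 0.195 for proliferation genes (1 higher and 5 lower of 21), 0.506 for ER stress genes (2 higher and 3 lower of 24), 0.214 for mitophagy and autophagy genes (2 higher and 6 lower of 29), 0.161 for lysosome genes (3 higher and 6 lower of 24), 0.6504 for nuclear oxidative phosphorylation genes (1 higher and 0 lower of 32), 0.513 for NRF2 and oxidative stress genes (2 higher and 3 lower of 19), 0.487 for p53 and apoptosis genes (2 higher and 4 lower of 20), 0.487 for Notch genes (4 higher and 4 lower of 14), 0.919 for thyroid hormone and cAMP response genes (3 higher and 3 lower of 17), 0.513 for clustered histone genes (1 higher and 1 lower of 7). Endocrine progenitor genes passed without KO replicate 1 (adjusted p = 0.0401, from 0.00453 to 0.528 over the alternatives). With fry, endocrine progenitor, proliferation, lysosome, Notch, and mitophagy and autophagy genes passed as lower (fry adjusted p = 0.0477 for the last). Epsilon and PP cell, intestine and stomach, and neuronal genes passed it as higher. Since 33.4% of all tested genes were called, a pass of fry does not set a list apart from other genes. The median and the camera direction differed in sign for ER stress and for thyroid hormone and cAMP response genes, and the median and mean for duct genes.

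The largest rises were in PENK, which encodes proenkephalin, and CDH13, a cadherin. PENK had 5 counts in wild type and 570 in knockout libraries, a ratio of 123 (95% counting interval 52.5 to 381). CDH13 rose 61.5-fold, followed by PCDHB5 at 25.9-fold, PCP4 at 19.6-fold, KCNV1 at 15.98-fold and CARTPT, a neuropeptide gene, at 14.1-fold. Counts of PCDHB5 can be split with its protocadherin paralogs. The zinc finger genes ZNF248 and ZNF875 had 0 counts in all knockout libraries, against 8.28 and 6.36 CPM in wild type, so they were at least 45.9-fold and 35.2-fold lower. TAC1, a tachykinin gene, had 4 counts in knockout and 489 in wild type libraries, a ratio of 113 (95% counting interval 43.9 to 417). GIP, an incretin gene, fell 78.3-fold, GPR119 76.5-fold and CNGA4 65.6-fold.

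Of 17436 genes tested by edgeR in the NKX2-2 experiment, 2888 were higher and 2936 lower in knockout, 1270 and 964 of them by at least 2-fold. With upper-quartile scaling, 3473 were higher and 2478 lower. The groups did not overlap in 45.5% of the genes, where chance gives 10%. With limma on log2(TPM + 1), which changes the values, the test and the filter together, 392 and 456 genes were higher and lower by at least 2-fold.

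**Figure D1:**
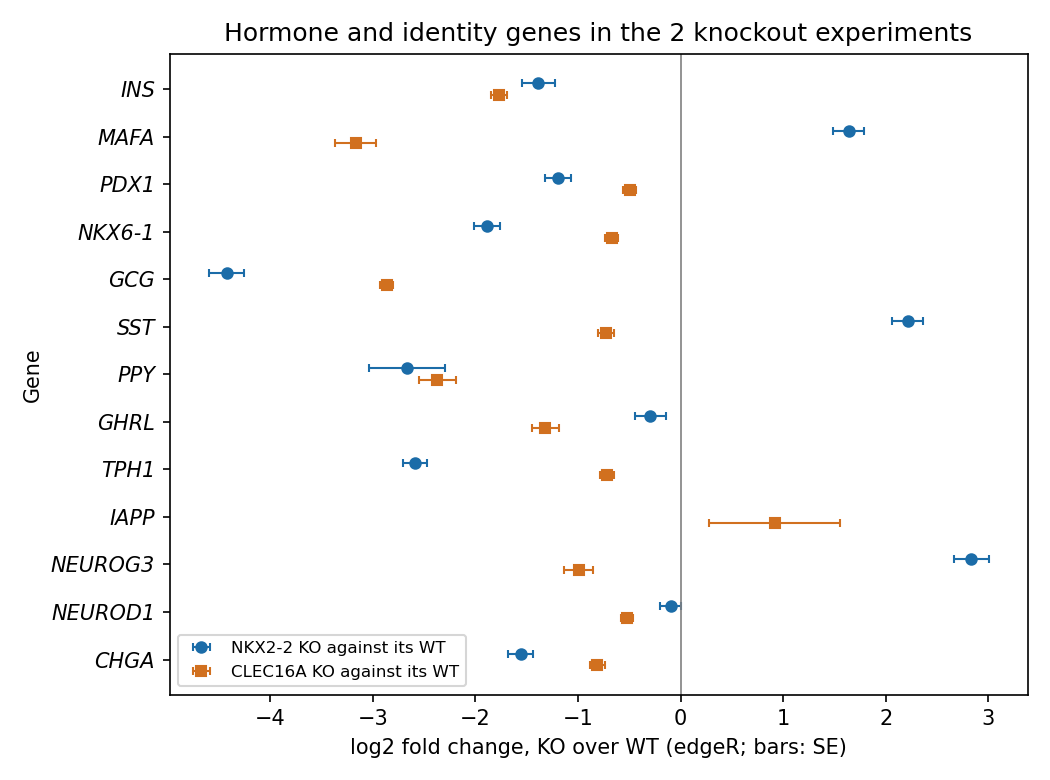
Log2 fold change of knockout over wild type (x axis; bars are SE) for hormone and identity genes (y axis), with circles for NKX2-2 and squares for CLEC16A, 3 libraries per group. GCG lies at -4.43 and -2.86, while SST lies at 2.21 and -0.73.

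The second comparison asked the same of cells labelled CLEC16A knockout. GCG fell 7.27-fold (264 ± 1.73 CPM in knockout and 1918 ± 44.6 CPM in wild type libraries), a log2 fold change of -2.86 (SE 0.06, adjusted p = 4.46e-19). MAFA, a transcription factor of mature beta cells, fell 8.98-fold, PPY 5.18-fold, INS 3.41-fold and GHRL 2.49-fold. Among liver and gut genes, AFP, which encodes alpha-fetoprotein, rose 4.05-fold (6971 ± 312 CPM in knockout and 1719 ± 42.7 CPM in wild type libraries), ALB (albumin) 6.61-fold and FABP2, an intestinal fatty acid binding protein, 11.6-fold.

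NEUROG3 had a log2 fold change of -0.99 (SE 0.14, adjusted p = 3.65e-06). Smaller falls were seen in CHGA (-0.81), SST (-0.73), TPH1 (-0.72), NKX6-1 (-0.67), NEUROD1 (-0.52) and PDX1 (-0.50), all past the edgeR test. The call of CHGA was lost with limma on log2(TPM + 1) with no filter, where its log2 fold change was -0.96 (SE 0.37, adjusted p = 0.149, and from 1.25e-40 over the 17 alternatives). IAPP, at 0.456 ± 0.105 CPM in knockout and 0.241 ± 0.2203 CPM in wild type libraries, did not pass it, with a log2 fold change of 0.92 (SE 0.64, adjusted p = 0.262).

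Of the 30 tested beta cell identity genes, 6 rose, 21 fell and 3 did not pass the test (6 higher and 21 lower adjusted over the list alone), with a median log2 fold change of -0.63 (camera adjusted p = 4.76e-05, and adjusted p = 0.07903 with an estimated correlation). INS (-1.77) had the smallest p, and MAFA had -3.17. Of the 14 tested alpha cell genes, 4 rose, 8 fell and 2 did not pass the test (4 higher and 8 lower adjusted over the list alone), with a median log2 fold change of -0.56 (camera adjusted p = 0.0206, and adjusted p = 0.116 with an estimated correlation). Its leading members went apart, GCG (-2.86) and DPP4 (1.64). The alpha cell call was lost with the replicate block (adjusted p = 0.0511; from 3.19e-05 to 0.116 over the 13 alternatives). Of the 12 tested genes of enterochromaffin-like cells, 0 rose, 9 fell and 3 did not pass the test (0 higher and 9 lower adjusted over the list alone), with a median log2 fold change of -0.73 (camera adjusted p = 2.69e-05, and adjusted p = 0.07903 with an estimated correlation). TRPA1 had -1.29 and FEV -0.82. Of the 17 tested endocrine progenitor genes, 1 rose, 16 fell and 0 did not pass the test (1 higher and 16 lower adjusted over the list alone), with a median log2 fold change of -0.72 (camera adjusted p = 1.70e-06, and adjusted p = 0.0521 with an estimated correlation). CDKN1A, a cell cycle inhibitor, was the member that rose (2.11), and PAX4 had -1.22. Of the 24 tested genes of secretory granules and exocytosis, 1 rose, 22 fell and 1 did not pass the test (1 higher and 22 lower adjusted over the list alone), with a median log2 fold change of -0.75 (camera adjusted p = 6.62e-09, and adjusted p = 0.07903 with an estimated correlation). They were led by PTPRN (-1.24) and PTPRN2 (-0.96). Of the 18 tested ion channel genes, 2 rose, 15 fell and 1 did not pass the test (3 higher and 15 lower adjusted over the list alone), with a median log2 fold change of -0.81 (camera adjusted p = 1.22e-04, and adjusted p = 0.116 with an estimated correlation). ABCC8, a subunit of the beta cell potassium channel, had -1.25, and ITPR3 1.23. Of the 17 tested neuronal genes, 0 rose, 16 fell and 1 did not pass the test (0 higher and 16 lower adjusted over the list alone), with a median log2 fold change of -1.12 (camera adjusted p = 2.08e-08, and adjusted p = 0.0463 with an estimated correlation). Examples were NCAM1 (-1.25) and CALB2 (-1.14). Of the 18 tested mesenchyme genes, 2 rose, 12 fell and 4 did not pass the test (2 higher and 13 lower adjusted over the list alone), with a median log2 fold change of -1.04 (camera adjusted p = 1.22e-04, and adjusted p = 0.0521 with an estimated correlation). The collagen genes COL3A1 and COL1A1 had -3.33 and -2.93.

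Of the 17 tested liver genes, 14 rose, 0 fell and 3 did not pass the test (14 higher and 0 lower adjusted over the list alone), with a median log2 fold change of 1.13 (camera adjusted p = 1.45e-07, and adjusted p = 0.0521 with an estimated correlation). ALB (2.72) and AFP (2.02) led. Of the 18 tested duct genes, 16 rose, 1 fell and 1 did not pass the test (16 higher and 1 lower adjusted over the list alone), with a median log2 fold change of 0.88 (camera adjusted p = 1.05e-06, and adjusted p = 0.101 with an estimated correlation). CLDN4, a tight junction gene, had 2.03 and TFF2 2.54. Of the 12 tested intestine and stomach genes, 8 rose, 2 fell and 2 did not pass the test (8 higher and 2 lower adjusted over the list alone), with a median log2 fold change of 1.08 (camera adjusted p = 0.00173, and adjusted p = 0.101 with an estimated correlation). These were led by FABP2 (3.53) and CDH17 (2.29). Of the 21 tested proliferation genes, 13 rose, 0 fell and 8 did not pass the test (15 higher and 0 lower adjusted over the list alone), with a median log2 fold change of 0.30 (camera adjusted p = 0.00167, and adjusted p = 0.162 with an estimated correlation). MKI67 had 0.82 and RRM2 0.64. Of the 7 tested clustered histone genes, 6 rose, 0 fell and 1 did not pass the test (7 higher and 0 lower adjusted over the list alone), with a median log2 fold change of 0.82 (camera adjusted p = 0.00293, and adjusted p = 0.109 with an estimated correlation). H1-2 had 0.82 and H4C8 1.08. Histone genes have near-identical copies. All histone genes together took 0.0933% ± 0.00056 of counts in knockout and 0.0921% ± 0.0014 in wild type libraries (exact permutation p = 0.3). The rise of the tested list genes was thus not seen in the total of histone counts.

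Of the 17 tested NF-kB and inflammation genes, 16 rose, 0 fell and 1 did not pass the test (17 higher and 0 lower adjusted over the list alone), with a median log2 fold change of 1.22 (camera adjusted p = 6.41e-09, and adjusted p = 0.0463 with an estimated correlation). ICAM1, an adhesion molecule, had 2.85 and CCL20, a chemokine, 2.61. Of the 28 tested interferon and antigen presentation genes, 22 rose, 4 fell and 2 did not pass the test (23 higher and 4 lower adjusted over the list alone), with a median log2 fold change of 0.93 (camera adjusted p = 1.05e-06, and adjusted p = 0.0463 with an estimated correlation). They included HLA-B (1.56) and TAP1 (1.70); HLA-B shares reads with other HLA genes. Of the 24 tested ER stress genes, 18 rose, 1 fell and 5 did not pass the test (19 higher and 1 lower adjusted over the list alone), with a median log2 fold change of 0.39 (camera adjusted p = 4.45e-05, and adjusted p = 0.142 with an estimated correlation). ATF3 had 1.60 and HERPUD1 0.82. Of the 25 tested lysosome genes, 18 rose, 1 fell and 6 did not pass the test (18 higher and 1 lower adjusted over the list alone), with a median log2 fold change of 0.44 (camera adjusted p = 6.46e-05, and adjusted p = 0.0521 with an estimated correlation). CTSA, a lysosomal enzyme, had 1.16. Of the 26 tested glycolysis and hypoxia genes, 21 rose, 0 fell and 5 did not pass the test (22 higher and 0 lower adjusted over the list alone), with a median log2 fold change of 0.64 (camera adjusted p = 1.89e-06, and adjusted p = 0.359 with an estimated correlation). Examples were LDHA (1.16) and VEGFA (1.04). Of the 32 tested nuclear oxidative phosphorylation genes, 13 rose, 0 fell and 19 did not pass the test (13 higher and 0 lower adjusted over the list alone), with a median log2 fold change of 0.13 (camera adjusted p = 0.0346, and adjusted p = 0.572 with an estimated correlation). SDHB had 0.56 and UQCRC2 0.43. The oxidative phosphorylation call was lost without KO replicate 2 (adjusted p = 0.1326) or WT replicate 1 (adjusted p = 0.1068), and with upper-quartile scaling (adjusted p = 0.0832). Over the 13 alternatives its adjusted p ran from 0.00837 to 0.572.

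Of the 20 tested p53 and apoptosis genes, 15 rose, 1 fell and 4 did not pass the test (15 higher and 1 lower adjusted over the list alone), with a median log2 fold change of 0.36 (camera adjusted p = 2.88e-04, and adjusted p = 0.0521 with an estimated correlation). CDKN1A had 2.11 and GDF15 1.84. Of the 19 tested NRF2 and oxidative stress genes, 9 rose, 2 fell and 8 did not pass the test (9 higher and 3 lower adjusted over the list alone), with a median log2 fold change of 0.24 (camera adjusted p = 0.0139, and adjusted p = 0.101 with an estimated correlation). SOD2 had 1.49 and HMOX1 1.31. Of the 21 tested immediate early genes, 14 rose, 0 fell and 7 did not pass the test (14 higher and 1 lower adjusted over the list alone), with a median log2 fold change of 0.57 (camera adjusted p = 2.63e-04, and adjusted p = 0.0521 with an estimated correlation). ZFP36 had 1.32 and ATF3 1.60. The other lists, mitophagy and autophagy among them, did not pass, with camera adjusted p of 0.768 for delta cell genes (4 higher and 4 lower of 9), 0.935 for epsilon and PP cell genes (4 higher and 4 lower of 9), 0.949 for pancreatic progenitor genes (7 higher and 6 lower of 14), 0.0857 for acinar genes (5 higher and 1 lower of 10), 0.147 for endothelium and blood genes (1 higher and 2 lower of 5), 0.677 for pluripotency genes (4 higher and 3 lower of 9), 0.543 for monogenic diabetes genes (13 higher and 14 lower of 29), 0.147 for mitophagy and autophagy genes (12 higher and 4 lower of 29), 0.768 for cholesterol synthesis genes (6 higher and 6 lower of 22), 0.698 for Notch genes (3 higher and 4 lower of 14), 0.0804 for thyroid hormone and cAMP response genes (9 higher and 3 lower of 18). With fry, all of these lists passed except pancreatic progenitor and Notch genes. Mitophagy and autophagy genes passed fry as higher (fry adjusted p = 0.00199), as did acinar and pluripotency genes (5.70e-05 each). The pluripotency list had a median log2 fold change of 0.018 but a mean of 1.24 (SD 3.84 over 9 genes). Its pass therefore does not show that most of its genes rose. Endothelium and blood genes passed as lower without KO replicate 1, 2 or 3 (adjusted p = 0.0162, 0.0442 and 0.0412, from 0.00446 to 0.359 over the alternatives). Thyroid hormone and cAMP response genes passed as higher without WT replicate 2 (adjusted p = 0.0378, from 5.54e-04 to 0.199). The median and the camera direction differed in sign for delta cell genes, and the median and mean for epsilon and PP cell genes.

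The largest rises were in the zinc finger genes ZNF594, ZFP42 and ZNF615, at 0 counts in all wild type libraries and at 8.61, 7.93 and 7.12 CPM in knockout, at least 94.6-fold, 87.1-fold and 78.2-fold higher. LRRC61 rose from 0.0477 to 34.8 CPM, ZBED6CL from 0.0995 to 35.95 CPM and FMO9P from 0.0774 to 7.796 CPM. ZBED6CL lies within LRRC61, so their reads cannot be separated. In the NKX2-2 experiment ZFP42, ZNF615, LRRC61 and ZBED6CL were tested too, with log2 fold changes of 0.51, 0.73, -0.26 and -0.47. ZNF594 had -5.05 there. The CLEC16A wild type libraries thus lacked, or nearly lacked, transcripts found in the other experiment, and these rises need not come from the knockout. ZNF875 and ZNF527, neighbours on chromosome 19, had 0 counts in all knockout libraries and were at least 169-fold and 55.6-fold lower. LINC02693 had 2 counts in knockout and 701 in wild type libraries, a ratio of 327 (95% counting interval 90.3 to 2709). COL15A1, a collagen gene, had 8 counts in knockout and 545 in wild type libraries, a ratio of 63.6 (95% counting interval 32.1 to 148). FIRRE fell 19.997-fold and BEX5 19.01-fold.

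Of 19958 genes tested by edgeR in the CLEC16A experiment, 4732 were higher and 4253 lower in knockout, 1745 and 1030 of them by at least 2-fold. The groups did not overlap in 53.8% of the genes, where chance gives 10%. Which direction held more genes depended on the settings. With upper-quartile scaling, 4034 were higher and 5294 lower, and in one fit of all libraries 3751 and 4196. With limma on log2(TPM + 1), which changes the values, the test and the filter together, 2988 were higher and 4612 lower, and the median log2 fold change of all tested genes was -0.12 in place of -0.011.

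**Figure D2:**
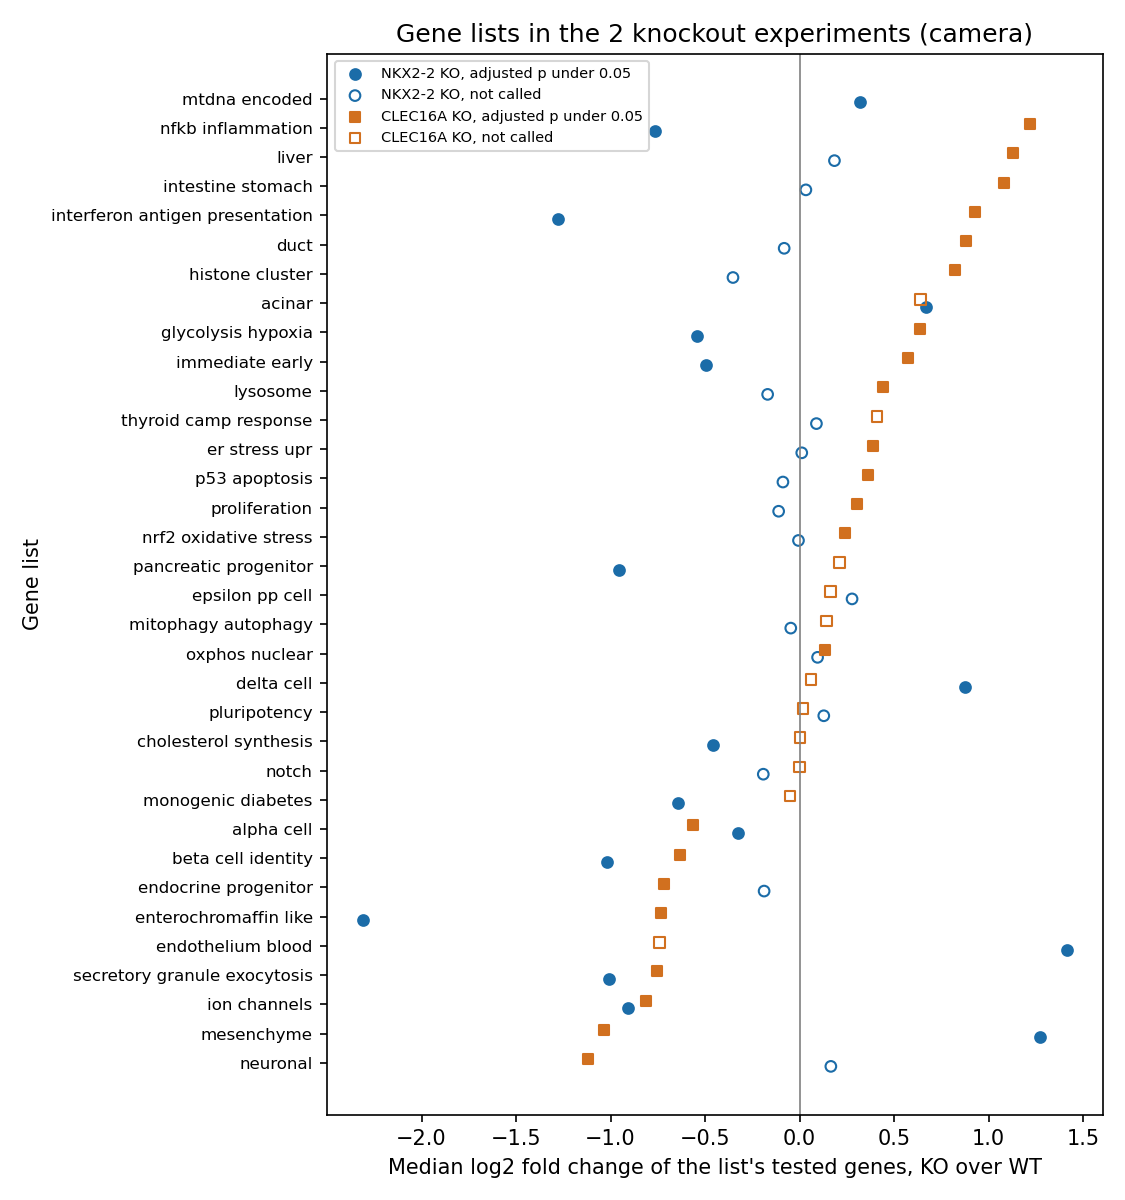
Median log2 fold change of knockout over wild type (x axis) for the tested genes of each of the 34 lists (y axis), with circles for NKX2-2 and squares for CLEC16A (none for mitochondrial DNA genes, at 0 counts there), filled where the camera adjusted p was under 0.05. Mesenchyme lies at 1.27 and -1.04, NF-kB and inflammation at -0.76 and 1.22.

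The third comparison set both knockout effects side by side. GCG, INS, PPY, TPH1, NKX6-1, PDX1 and CHGA fell in both. SST, NEUROG3 and MAFA rose with NKX2-2 knockout and fell with CLEC16A knockout, and for each the difference of the log2 fold changes passed the interaction test (2.97, 3.85 and 4.83). Among 16975 genes tested in both, 968 were lower in both, where independent lists give 697, and 513 were higher in both, where they give 660.0. Another 863 genes were higher with NKX2-2 and lower with CLEC16A knockout (616 from independent lists), and 1155 the other way round (747 from independent lists). Fisher's exact test gave p = 3.60e-36, 2.19e-13, 2.71e-33 and 7.15e-75 for these 4 overlaps in turn. It counts genes as independent, which they are not, so these p-values describe the overlaps and do not measure the spread between libraries. The numbers from independent lists also take every gene as equally easy to call in both experiments. The shortfall of genes higher in both was not seen among genes changed at least 2-fold in both, where 92 were shared and independent lists give 81.3 (Fisher's exact p = 0.2099). Fold changes of both experiments had a Pearson correlation of -0.08 and a Spearman correlation of -0.10 across genes, which are not independent replicates. The interaction test by edgeR called 7923 of 20257 genes, with the NKX2-2 effect higher in 3841 and lower in 4082.

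The wild type libraries of both experiments differed as well. Between them 9711 genes, 51.6% of 18829, passed the edgeR test, and their mean log2 CPM had a Pearson correlation of 0.91 across genes. Levels were therefore compared only within an experiment, and the knockout effects only as differences from each experiment's own wild type.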

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

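Of 99 named genes in the interaction test of edgeR over the 12 libraries, 88 differed between both knockout effects (adjusted p under 0.05). Over all genes tested, 7923 of 20257 (39.1%) differed. Many of the named genes were picked for large or clear changes in either experiment, so their higher share is built in. Among the 88, PENK and CARTPT were too low to be tested in the CLEC16A experiment alone, and FMO9P in the NKX2-2 experiment alone. Values in parentheses are the NKX2-2 effect minus the CLEC16A effect on the log2 scale. Groups of 3 libraries are too small for a search for outlying samples. Fitted values of genes at 0 counts in a group depend on the prior count and are no bounds.

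The NKX2-2 effect was higher in LINC02693 (8.30), COL15A1 (7.02), KDR (6.52), PENK (6.51), CDH13 (6.36), PCDHB5 (6.07), PCP4 (5.70), KCNV1 (5.40), PDGFRA (5.21), FIRRE (5.06), BEX5 (5.001), CARTPT (4.91). It was also higher in MAFA (4.83), COL3A1 (4.79), COL1A1 (3.90), NEUROG3 (3.85), CLDN5 (3.27), LUM (3.14), CLPS (3.14), SST (2.97), LEPR (2.69), NCAM1 (1.97), FRZB (1.77), GHRL (1.05), PRSS2 (0.83), NKX2-2 (0.63), PAX4 (0.62), NEUROD1 (0.46), PTPRN2 (0.45). It was lower in ZNF594 (-15.90), ZFP42 (-10.11), ZNF615 (-9.74), LRRC61 (-9.56), ZNF248 (-9.05), ZBED6CL (-8.88), TAC1 (-7.49), FMO9P (-6.40), ICAM1 (-5.41), GPR119 (-5.27), CNGA4 (-4.76), GIP (-4.30), ITPR3 (-4.22), CCL20 (-3.84), PCSK1 (-3.68). Lower values followed for FOS (-3.65), MX1 (-3.64), FABP2 (-3.42), CLDN4 (-3.41), ALDOC (-3.25), SYT13 (-3.02), GDF15 (-2.85), HLA-B (-2.81), CXCL8 (-2.69), CDH17 (-2.62), TFF2 (-2.59), IRX1 (-2.57), ADRA2A (-2.57), IFI6 (-2.32), CDKN1A (-2.29), ZFP36 (-2.21), LMX1A (-2.18). The remaining lower ones were LDHA (-2.13), HMOX1 (-2.11), TRPA1 (-2.08), SOD2 (-2.03), VEGFA (-1.96), DHCR7 (-1.85), TPH1 (-1.85), AFP (-1.84), SLC18A2 (-1.84), DPP4 (-1.81), ALB (-1.76), MNX1 (-1.70), ATF3 (-1.63), FEV (-1.61), GCG (-1.54), CALB2 (-1.34), and CTSA (-1.33), ENO2 (-1.24), MKI67 (-1.24), NKX6-1 (-1.19), NR4A2 (-1.06), RRM2 (-0.93), H1-2 (-0.93), HERPUD1 (-0.79), CHGA (-0.72), PDX1 (-0.67), SDHB (-0.57).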

How the results depend on the processing

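Leaving out single libraries kept each count of changed genes within 1.5 times of its value. No call of a named gene turned its direction past the threshold. Counts moved by more with limma on TPM, which changes the values, the test and the filter together. With limma on log2(TPM + 1), log2(TPM + 0.1) and log2(TPM + 1) with no filter, genes higher at least 2-fold with NKX2-2 knockout numbered 392, 664 and 392, and genes higher with CLEC16A knockout 2988, 2937 and 2813. With log2(TPM + 1), filtered and not, genes lower at least 2-fold with NKX2-2 knockout numbered 456 and 461, and genes higher at least 2-fold with CLEC16A knockout 1094 and 1118. With no filter, 1790 genes were higher and 1757 lower with NKX2-2 knockout. The cause was not tested. Asking for 2-fold in both experiments left fewer genes by construction: 141 lower in both (49.2 from independent lists), 203 higher with NKX2-2 and lower with CLEC16A knockout (50.9 from independent lists) and 198 the other way round (78.6 from independent lists). It left 92 genes higher in both, above the 81.3 of independent lists (Fisher's exact p = 0.2099), while without that limit they were fewer than independent lists give; the cause of this turn was not tested.

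With an estimated correlation, 0 lists were higher and 2 lower with NKX2-2 knockout, and 2 higher and 1 lower with CLEC16A knockout; fry called 8 higher with NKX2-2 knockout. Among results that did not pass the test, directions turned for IAPP with CLEC16A knockout (-0.15, log2(TPM + 1) with no filter), for CLEC16A with NKX2-2 knockout (-0.069 to 0.14 over left-out libraries) and for some lists, given as adjusted p. These were thyroid hormone and cAMP response with NKX2-2 knockout (0.957 with the replicate block, 0.743 without both libraries numbered 3, 0.704 to 0.936 over left-out libraries), pancreatic progenitor with CLEC16A knockout (0.555 with fry, 0.822 to 0.991 over left-out libraries), and, over left-out libraries, intestine and stomach (0.569 to 0.9995) and nuclear oxidative phosphorylation (0.198 to 0.915) with NKX2-2 knockout, and epsilon and PP cell (0.822 to 0.996) and Notch (0.638 to 0.997) with CLEC16A knockout.

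Medians of some lists that did not pass turned sign with the scaling: ER stress with RLE, and with upper-quartile scaling mitophagy and autophagy and NRF2 with NKX2-2 knockout, and cholesterol synthesis, delta cell and pluripotency with CLEC16A knockout. The rule for pairing by replicate number, a correlation over 0.1 in every pair, was not met: deviations of same-numbered libraries correlated by 0.11, 0.03 and 0.32 in the NKX2-2 and 0.01, 0.01 and -0.03 in the CLEC16A experiment. In the NKX2-2 experiment the libraries numbered 3 did deviate together (0.32), so a shared handling of these is open. Their correlations of -0.11 to -0.24 to the libraries of other numbers in the opposite group add nothing to this. Deviations from a mean of 3 libraries sum to 0, which pulls these values below 0 by construction. With the replicate block, 4077 genes were higher and 3960 lower with NKX2-2 knockout, 4626 and 4137 with CLEC16A knockout, and 8970 differed between the effects. Without both libraries numbered 3, an alternative chosen after seeing the data, 2883 genes were higher and 3104 lower with NKX2-2 knockout; without genes short of counts 2900 and 2942, and without mitochondrial DNA genes 2754 and 3041. Depth limits the NKX2-2 experiment more, where 3 counts are 0.145 to 0.186 CPM.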

Other observations

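The count of zinc finger genes and the tests of the mesenchyme list and of the targets' own transcripts were chosen after the result was seen; the tests on TPM, scaling, library correlations and other splits were written before.

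A first pattern is a set of all-or-none genes, at 0 counts in all 3 libraries of one group and at a mean of at least 1 CPM in the other: 11 in the NKX2-2 and 10 in the CLEC16A experiment. Reads lost by the counting are argued against, since the median ratio of TPM between the groups was 0 in both experiments and no gene reached a ratio of 0.1. Zinc finger genes were 4 of the 6 protein-coding ones in the first (438 of 14561 tested) and 5 of 7 in the second (451 of 15224); this class was picked because it stood out among them, so Fisher's exact two-sided p of 1.15e-05 and 4.46e-07 describe it and are no evidence for a cause. The neighbours ZNF875 and ZNF527 (chromosome 19, 37312837 to 37393066), at 0 in the knockout libraries of both experiments, are among them each time. ZFP42 and ZNF615, at 0 in the CLEC16A wild type, had log2 fold changes of only 0.51 and 0.73 in the NKX2-2 experiment. Their absence was thus not shared by the other wild type, and a loss in the CLEC16A wild type is open. Whether the all-or-none genes were switched by the knockout or by growth from single cells also stays open, as do reads lost at the alignment, which would leave both tables at 0.

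A second pattern in CLEC16A knockout is that camera called the liver, gut and duct lists higher and the beta and alpha cell lists lower, while the delta cell and the epsilon and PP cell lists did not pass; none of these 5 calls held with an estimated correlation (adjusted p from 0.0521 to 0.116). Lists of other cell types did not all rise alike. The mesenchyme list had a median of -1.04 (SD 1.59 over 18 genes) and the neuronal list of -1.12 (SD 0.68 over 17 genes). That of the liver list was 1.13 (SD 1.17). Camera with an estimated correlation gave adjusted p = 0.0521 for mesenchyme and 0.0463 for neuronal genes. The permutation p of 4.00e-05 for each against liver only describes this gap, since the lists had been seen and their genes are not independent. How far the neuronal genes come from endocrine cells is not known here, so a lower share of endocrine cells stays open. Over 3 scalings the lowest liver median was 1.06, and the alpha cell median stayed below 0. These scalings differed too little to turn either sign, so a larger scaling error is not excluded by them. A scaling factor shifts all lists nearly alike, so the gap between these lists hardly depends on it. A rise of endoderm cells of other fates, or a change of expression within cells, stays open and was not tested.

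Another pattern is that neither targeted transcript passed the edgeR test in its own knockout, although NKX2-2 was lower in every alternative and had a log2 fold change of -0.74 on log2(TPM + 1). A single mislabelled library is argued against, since all 12 libraries correlated better with each library of their own group than with any of the other. An exchange of all knockout with all wild type labels of an experiment would leave these correlations the same and was not tested. A transcript made without functional protein and an exchange of the experiments cannot be told apart here, because counts per gene do not show the edited site; NKX2-2 had a log2 fold change of -0.93 in the CLEC16A experiment.

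With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real split gave 5824 genes for NKX2-2, 8985 for CLEC16A and 9711 between the wild types, and the highest of the other splits gave 0 in each; 1 of the 10 splits, the real one, reached the real count. For the lists, the real splits called 17 and 22 and the highest others 12 and 17. Each other split mixes the groups unevenly, so it keeps part of their difference and widens the spread within each side. Neither the 0 genes nor the list calls of these splits therefore show what chance alone would give. For the interaction, 1 of 100 groupings (the real one) gave 7923 genes or more, and the highest other, 6960, kept both real splits and turned one round. Since the count followed the number of real splits kept, these regroupings break the knockout effects themselves and cannot say whether chance is excluded for their difference. Regroupings that kept 1 real split gave 1047 to 3138 genes, and the 82 that kept neither gave 0.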
